A study of Mus musculus with 12 samples.

How the data were processed

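RNA was measured in 12 libraries of dissected CA1 tissue of the mouse hippocampus, 6 from mice with a ligated coronary artery (myocardial infarction, MI) and 6 from sham-operated mice, with polyadenylated RNA sequenced as single-end reads of 50 bases, per the labels' protocols. FastQC 0.11.5, STAR 2.5.2b, featureCounts and Subread 1.5.1 and the mm10 build are named in the submitters' processing notes, without their order or settings. The deposited count files hold whole-number read counts per Ensembl gene, not normalized, for 48709 gene IDs in each library. Whether strand was used in counting is not given in the sources used here, so reads of overlapping or antisense genes may not be told apart. The authors also deposited a pair of gene tables, 1 of genes higher in MI and 1 of genes lower, with a log2 fold change, an adjusted p-value and log2-scale expression values per library; how the authors made these values is not given in the sources used here. The deposited log2 fold change equals the difference of the deposited library means to within 5.00e-09.

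Symbols and coordinates came from GENCODE M21 on the same build for 48349 of the 48709 IDs, and the coordinates printed are from that annotation. Library totals ran from 20764133 to 35643127 counts. Genes were kept by edgeR's filterByExpr, which left 16829, and scaled by TMM. MI was compared with Sham in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust dispersion, without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression levels are counts scaled to library size (edgeR CPM), given as mean ± SD over 6 libraries, log2 fold changes as MI minus Sham with the standard error (SE) from the quasi-likelihood fit, and log2 CPM used a prior count of 2.

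Gene lists of cell type and region markers, pathways and complexes, 35 in all, were fixed before the data were examined; 3 of their symbols were matched through older names and 13 genes stood in more than 1 list. Lists with at least 4 tested members were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Beside it stood camera with a correlation estimated per list, fry, and an exact two-sided permutation test of the mean log2 CPM of the list. The exact test used all 924 splits of the libraries, and its smallest possible p is 0.0021645. At that p a single list could not pass after adjustment over all 35 lists. The genes named were also set by rule before the data were examined: those past the threshold with a mean of at least 50 counts and an ordinary symbol, 10 in each direction, with empty places filled by the smallest unadjusted p; 4 members of each list with the smallest p, and the members that a count of 5 or fewer covers; the 5 genes with the smallest adjusted p in each of the authors' tables; and the 5 largest fold changes in each direction among genes past the threshold, of which there were 0. Other genes named were chosen after their values were seen, and this is said where they appear.

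The alternatives were DESeq2 1.42.0, other library scalings, no or a stricter filter on low counts (at least 50 counts in at least 6 libraries), the replicate number as a block, 1 or 2 surrogate variables (sva 3.50.0), limma-voom with sample weights, and leaving out each library in turn. After the data were examined, further alternatives were added: the sex-linked set of the libraries as a covariate or each set alone, marker scores as covariates, leaving out Sham 1 and Sham 6, and 37 fits with library-level factors subtracted or entered as covariates. The labels do not give the sex of the animals. Libraries were grouped by which was larger, the counts of Y-linked genes or those of Xist, and are called libraries with Y-linked counts and libraries with Xist. The former held 18 to 50 Xist counts and the latter 1 to 7 Y-linked counts, and these sets are not groups of the study.

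The procedure was tested on simulated data in which 200 genes were changed, 50 per fold. The changed genes were drawn from those with a mean of at least 50 counts, so recovery at lower counts was not measured. Each simulation was drawn once. With negative binomial counts for 16671 tested genes, the MI against Sham test recovered 18% of genes changed 1.2-fold, 74% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, with 2 false calls. In real counts with the groups mixed and changes made by thinning, over 16829 genes, it recovered 28%, 80%, 88% and 98%, with 2 false calls. No library pair within a group was a duplicate: the chi-square per degree of freedom of their counts ran from 6.27 to 79.8 over 30 pairs. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries.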

Results

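Gene expression in dissected hippocampal CA1 tissue was compared between 6 libraries from mice with myocardial infarction (MI) and 6 libraries from sham-operated mice (Sham). CA1 is the hippocampal field whose pyramidal neurons carry much of its output, and the series title links heart failure, memory and the control of gene expression. Library totals ran from 20764133 counts in Sham 1 to 35643127 in Sham 5. Y-linked counts exceeded those of Xist, a transcript of the inactive X chromosome, in MI 1, MI 3, MI 4, Sham 1, Sham 2 and Sham 3, and Xist counts exceeded Y-linked counts in the other 6 libraries, so each group held 3 libraries of each kind.

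Which transcripts of CA1 tissue differ after MI was asked by comparing MI with Sham. Transcripts of myelin were higher in MI as a group, with a median log2 fold change of 0.50 and 16 of 16 genes positive. Their score in MI minus Sham was 0.85 in the libraries with Y-linked counts and 0.15 in those with Xist. Transcripts of the nuclear-encoded respiratory chain were slightly higher, with a median of 0.10 and 72 of 76 positive. Both groups passed a test that presets the correlation between genes. Neither passed with an estimated correlation (adjusted p = 0.154 and adjusted p = 0.436). The preset test called 10 lists in MI against Sham, and a median of 10 in other splits of the 12 libraries. Fibroblast and meningeal markers were lower by the same test, with a median of -0.93, but not with an estimated correlation (adjusted p = 0.436). They were highest in Sham 1, and their score in MI minus Sham was -1.92 in the libraries with Y-linked counts and 0.32 in those with Xist. Genes of synaptic plasticity and of histone H3K4 methylation did not pass as groups, and edgeR called no single gene, where DESeq2 called 11.

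Of 16829 genes, 0 were higher and 0 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.597. At an unadjusted p under 0.05 there were 1270 genes, 665 higher and 605 lower in MI, where 841 were expected. DESeq2 called 11 genes, 7 higher and 4 lower, and all 11 are in the authors' deposited tables; limma-voom called 0. The 7 higher ones were A330015K06Rik and Adssl1 (DESeq2 adjusted p 0.0134 for both), Sec14l5, Smtn and Neat1 (0.0395 for each), and 1110032F04Rik and Nkx6-2 (0.0487 for both). The 4 lower ones were Cbx5 and Dnah1 (0.0395 for both) and C2cd4c and Gm2824 (0.0487 for both). Those among the 11 that the rule for named genes does not cover were named after their values were seen. The median biological coefficient of variation was 11.3%.

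The genes with the smallest p that were higher in MI included a purine nucleotide enzyme, an actin-binding protein and a nuclear RNA, none of which passed the threshold in edgeR and all of which passed it in DESeq2. Adssl1 (ENSMUSG00000011148, chromosome 12, 112620045 to 112641360, mm10), a muscle-type enzyme of adenosine monophosphate synthesis, had 15.9 ± 1.94 CPM in MI and 10.9 ± 1.73 in Sham (SD, n = 6 each), a log2 fold change of 0.54 (SE 0.11), with Sham 4 standing 0.38 log2 above the other Sham libraries. Its edgeR adjusted p was 0.597, as it was for each of the 20 genes in this paragraph and the next. Smtn, which encodes the actin-binding protein smoothelin, had a log2 fold change of 0.42 (SE 0.08), and Neat1, the RNA scaffold of paraspeckles, had 0.39 (SE 0.08) with 150.2 ± 14.5 CPM in MI and 114.2 ± 14.4 in Sham. Nkx6-2, a homeobox factor of oligodendrocytes, had 0.77 (SE 0.18), Tnni1, a troponin of slow muscle, 0.66 (SE 0.15), and Sec14l5 0.56 (SE 0.12). Pradc1 had 0.31, the kinase gene Pim3 0.27, the deubiquitinase gene Josd2 0.26 and Ndufa7, a subunit of respiratory complex I, 0.23. In each of these 10 genes all 6 MI libraries lay above the Sham median. The genes were picked for a small p in these same libraries, which favours such a separation.

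On the lower side, C2cd4c had the largest difference of the 10, with 13.3 ± 1.95 CPM in MI and 22.1 ± 5.96 in Sham (SD, n = 6 each) and a log2 fold change of -0.73 (SE 0.17). Tshz1, a zinc finger factor, had -0.62 (SE 0.15), Dnah1, a heavy chain of axonemal dynein, -0.46 (SE 0.10), and Tenm1, a teneurin of the neuronal surface, -0.42 (SE 0.10). Lypd1 had -0.35, Nol4 -0.26, Dnmbp -0.23, Twsg1, a modulator of bone morphogenetic protein signalling, -0.22, Smarca1, a chromatin remodelling ATPase, -0.21, and Bhlhb9 -0.20. In each of these 10 genes 0 of the 6 MI libraries lay above the Sham median, which the same pick by p favours.

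Genes of myelin were called higher in MI as a group by camera with the preset correlation, but not with an estimated one. All 16 measured members of the oligodendrocyte and myelin list had positive log2 fold changes with a median of 0.50, and 15 passed the threshold adjusted over the list alone, against 0 over all genes. Opalin had 26.1 ± 3.52 CPM in MI and 16.9 ± 4.72 in Sham (SD, n = 6 each), a log2 fold change of 0.63 (SE 0.16). Cldn11, which seals the layers of the sheath, had 0.50 (SE 0.14), Mag, an adhesion protein of the sheath, 0.53 (SE 0.16), and Fa2h, which makes hydroxylated myelin lipids, 0.49 (SE 0.15). The camera adjusted p over 35 lists was 1.05e-25 with the preset correlation, adjusted p = 0.154 with an estimated correlation, and 0.189 in the exact permutation test (unadjusted p 0.0108). The myelin score was low in Sham 1, Sham 2 and Sham 3, at -0.55, -0.69 and -0.45 log2 units from the mean of all libraries, and the list score differed by 0.85 between MI and Sham in the libraries with Y-linked counts and by 0.15 in those with Xist. Oligodendrocyte precursor markers had a median of 0.07, with 8 of 12 positive, a camera adjusted p of 0.0330, and adjusted p = 0.547 with an estimated correlation. Their 4 members with the smallest p included Sox10 at 0.35 and Olig1 at 0.23, transcription factors of the whole oligodendrocyte lineage. The precursor call ended without MI 1 (adjusted p 0.0504), MI 4 (0.0800), MI 5 (0.108), Sham 1 (0.0557), Sham 2 (0.0701), Sham 3 (0.108) or Sham 5 (0.0603). Camera's direction turned in the Xist libraries alone (0.897), where the list score in MI minus Sham was 0.0047. These are among 16 of 30 alternatives with the preset correlation that ended the call and 1 that turned it.

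**Figure D1:**
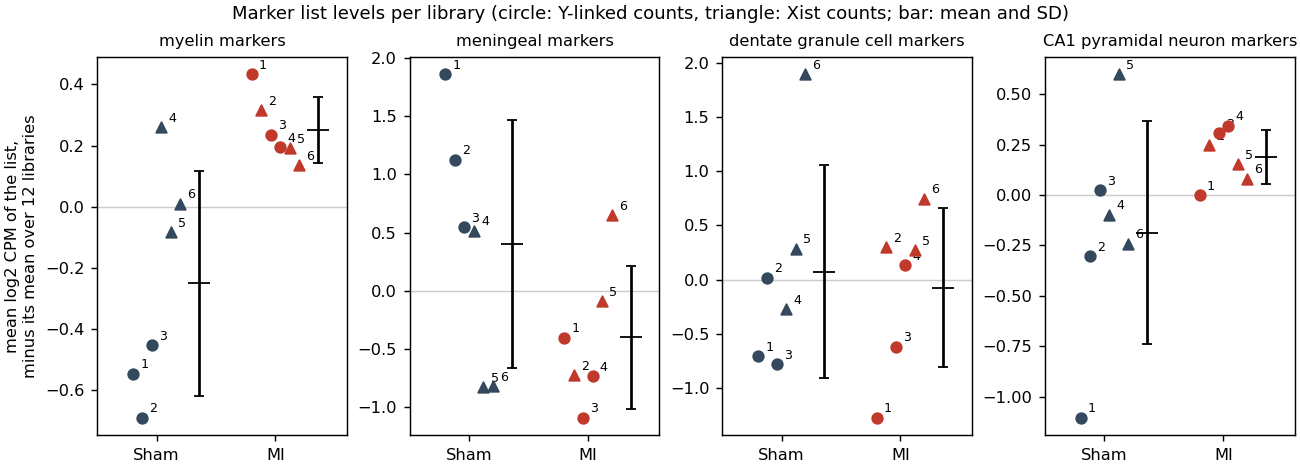
Each point is 1 library, its height the mean log2 CPM of a marker list minus the mean over 12 libraries, with circles for libraries with Y-linked counts, triangles for those with Xist, numbers for the replicate and bars for the group mean and SD (n = 6). Sham 1, Sham 2 and Sham 3 have the lowest myelin scores (-0.55, -0.69 and -0.45), Sham 1 has the highest meningeal score (1.86) and Sham 6 the highest dentate score (1.89).

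Subunits of the respiratory chain and of the ribosome were slightly higher in MI, called as groups with the preset correlation but not with an estimated one. Of 76 nuclear-encoded oxidative phosphorylation genes, 72 had positive log2 fold changes, with a median of 0.10, and 0 passed over all genes or adjusted over the list alone. Cox6a1, of complex IV, had 0.21 (SE 0.06), and Ndufa13 and Ndufb8, of complex I, had 0.16 (SE 0.05) and 0.16 (SE 0.05). The camera adjusted p was 5.05e-18, adjusted p = 0.436 with an estimated correlation, and 0.253 in the exact permutation test. Cytosolic ribosomal proteins had 64 of 79 positive and a median of 0.06, with Rps15 at 0.13 and Rps21 at 0.16; the camera adjusted p was 0.000279, and adjusted p = 0.436 with an estimated correlation. The ribosomal call ended in the Xist libraries alone (0.197). Proteasome subunits had 27 of 32 positive and a median of 0.04, with Psmb5 at 0.15; the camera adjusted p was 0.0299, and adjusted p = 0.850 with an estimated correlation. The proteasome call ended without MI 1 (0.115), MI 3 (0.230), MI 4 (0.0579), Sham 4 (0.0744) or Sham 6 (0.567), and in 11 of 30 alternatives in all. Genes encoded by the mitochondrion itself were not called, with a median of -0.03, a mean of 0.0015 and a camera adjusted p of 0.701.

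Genes that respond to glucocorticoids and to oxidative stress were also called higher with the preset correlation, but not with an estimated one. The glucocorticoid list had 18 of 25 positive and a median of 0.14, with 1 gene, Hif3a, past the threshold adjusted over the list alone and 0 over all genes. Hif3a had 8.02 ± 1.15 CPM in MI and 6.04 ± 0.44 in Sham (SD, n = 6 each), a log2 fold change of 0.41 (SE 0.10). Tsc22d3, the glucocorticoid-induced leucine zipper, had 0.26 (SE 0.09) and Arrdc2 0.27 (SE 0.08). The camera adjusted p was 0.000119, and adjusted p = 0.410 with an estimated correlation. The glucocorticoid call ended in the libraries with Y-linked counts alone (0.149). Oxidative stress genes had 26 of 36 positive and a median of 0.04, with Gpx4, a peroxidase of membrane lipids, at 0.20 and Prdx5 at 0.14; the camera adjusted p was 0.00875, and adjusted p = 0.154 with an estimated correlation (unadjusted p 0.00878). The oxidative stress call ended in the Xist libraries alone (0.126).

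Markers of neighbouring tissue differed between libraries. Fibroblast and meningeal markers were lower in MI, with 14 of 14 negative and a median of -0.93, among them Col1a1 at -0.79 and Ogn at -1.51; the camera adjusted p was 4.37e-09, and adjusted p = 0.436 with an estimated correlation. Their score in MI minus Sham was -1.92 in the libraries with Y-linked counts and 0.32 in those with Xist, where the list turned direction (camera adjusted p 0.0982). CA1 pyramidal neuron markers had a median of 0.18, with 12 of 14 positive and Gpr161 at 0.52, a camera adjusted p of 0.00235, and adjusted p = 0.597 with an estimated correlation; Sham 1 had the lowest CA1 score, -1.10. The CA1 call ended in 5 of 30 alternatives: with DESeq2 (0.0554), 2 surrogate variables (0.370) or the dentate and meningeal scores as covariates (0.616), without Sham 1 and Sham 6 (0.324), and in the Xist libraries alone (0.759). Dentate granule cell markers had a median of -0.47 and a camera adjusted p of 0.0330, adjusted p = 0.850 with an estimated correlation, and their direction turned when Sham 6 was left out (adjusted p 0.637). The dentate call also ended without MI 1 (0.277), MI 3 (0.165) or Sham 5 (0.0721); of 30 alternatives, 6 ended it, 1 of them by construction since the dentate score was itself a covariate, and 3 turned it. None of the 16 marker lists passed the exact permutation test, where the smallest adjusted p was 0.173; without Sham 4, 1 passed, the myelin list (exact permutation, adjusted p 0.0346).

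**Figure D2:**
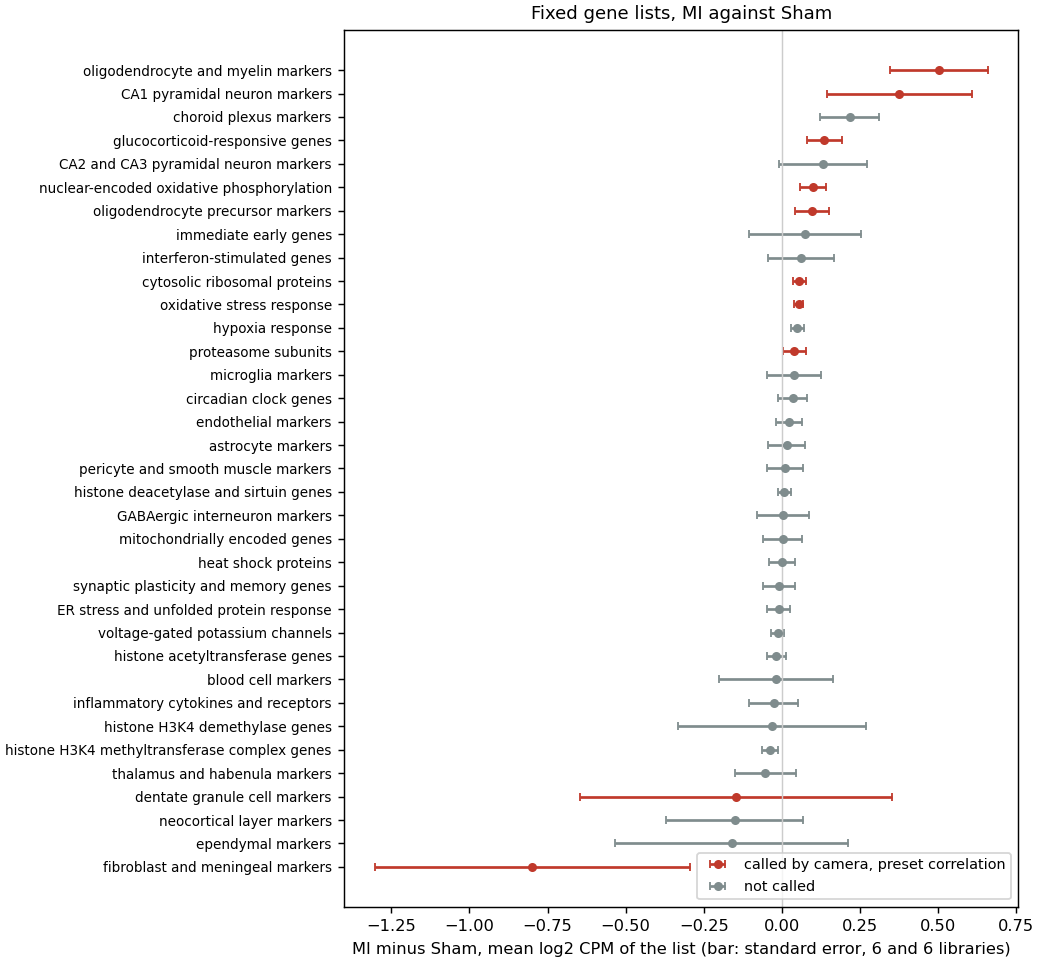
Points show the mean log2 CPM of each of 35 gene lists in MI minus Sham and bars its standard error (6 and 6 libraries), in red where camera with the preset correlation called the list. Myelin markers lie highest at 0.50 and fibroblast and meningeal markers lowest at -0.80.

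The lists closest to memory and to chromatin did not pass in camera on edgeR's fit of all 12 libraries without covariates. Synaptic plasticity and memory genes had 22 positive and 28 negative log2 fold changes and a median of -0.01 (camera adjusted p 0.369), with Cacna1c, an L-type calcium channel, at -0.34 (SE 0.10) and Reln, the secreted protein reelin, at -0.49 (SE 0.15). This list was called lower in 3 of 30 alternatives: with 2 surrogate variables (0.000474) or the dentate and meningeal scores as covariates (0.00912), and in the Xist libraries alone (0.0250). Histone H3K4 methyltransferase complex genes had 20 of 24 negative and a median of -0.04 (camera adjusted p 0.239), and H3K4 demethylase genes 7 of 8 negative and a median of -0.05 (0.465). Histone acetyltransferase genes had a median of -0.03 (0.540) and deacetylase and sirtuin genes 0.02 (0.601). ER stress genes had a median of -0.01 (0.701), with Atf4 at 0.10, immediate early genes 0.06 (0.369), hypoxia genes 0.05 (0.147), interferon-stimulated genes 0.04 (0.165) and inflammatory cytokines and receptors -0.03 (0.921). The median log2 fold changes of microglia markers (0.03, camera adjusted p 0.383) and astrocyte markers (0.00, 0.600) were near 0. Among the astrocyte markers, Aqp4, the water channel of astrocyte endfeet, had -0.25 (SE 0.07) and Ntsr2 had 0.16 (SE 0.07). With limma-voom and sample weights, camera called the interferon-stimulated genes (0.00122), the immediate early genes (0.00736) and the microglia markers (0.00370). Interferon-stimulated genes were also called without MI 1 (0.0281), MI 3 (0.00505) or Sham 1 (0.0116), immediate early genes without MI 1 (0.0341) or Sham 1 (0.0136), H3K4 methyltransferase genes without Sham 1 (0.0143) and microglia markers without Sham 6 (0.0355). In all, of 30 alternatives, 8 called the interferon list, 6 the immediate early genes, 3 the H3K4 methyltransferase genes, 2 the microglia markers and 2 the hypoxia genes.

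The remaining lists were CA2 and CA3 neurons (camera adjusted p 0.0922, with Cdh24 past the threshold adjusted over the list alone at 0.44), choroid plexus (0.105), neocortex (0.239), endothelium (0.357), thalamus and habenula (0.597), circadian clock (0.597), potassium channels (0.600), interneurons (0.701), heat shock proteins (0.756), blood (0.809), ependyma (0.849) and pericytes (0.921). Of these, CA2 and CA3 markers were called without MI 1 (0.0199), MI 2 (0.0196), MI 5 (0.0112), Sham 1 (0.0248) or Sham 2 (0.0342), choroid plexus markers without Sham 4 (0.0225), neocortex markers without Sham 5 (0.00717), endothelial markers without Sham 1 (0.0456) and ependymal markers without MI 3 (0.0261). In all, of 30 alternatives, 9 called the CA2 and CA3 markers, 3 the choroid plexus, 2 the neocortex and 2 the endothelial markers, and 1 the circadian genes. Interneuron markers and heat shock proteins had a negative median and camera direction up, and blood and ependymal markers a positive median and camera direction down.

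The authors' deposited tables list 542 genes as higher and 517 as lower in MI, with small changes: the median log2 fold change is 0.19 among the higher and -0.15 among the lower, and 935 of the 1059 lie under 0.3 in size. Of these genes 1025 were tested from the counts; 985 (96.1%) had the same sign, 444 had an unadjusted p under 0.05 and 0 passed edgeR's adjusted threshold. Across these genes, which are not independent replicates and were chosen on these libraries, Pearson's r between both sets of fold changes was 0.814 and Spearman's rho 0.876. In the authors' deposited table of higher genes the smallest adjusted p belong to Gjb6, a connexin of astrocytes (log2 fold change 0.22), Vwf, the endothelial von Willebrand factor (0.55), Rin2 (0.23), A330015K06Rik (0.31) and Adgrd1 (0.39). In the authors' deposited table of lower genes they belong to Pcdh19, a protocadherin (-0.34), the carbonic anhydrase gene Car12 (-0.43), Usp11 (-0.20), Gm2824 (-0.32) and Tnr, the matrix protein tenascin R (-0.18). From the counts Gjb6 had -0.01 (SE 0.14), opposite in sign to its deposited value, and Tnr -0.09 (SE 0.12). A330015K06Rik, annotated as antisense, had 0.81 (SE 0.13) with the smallest p of all genes, 3.70e-05.

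Set against the fixed lists, the authors' higher genes held 12 myelin genes where 0.50 were expected (Fisher's exact test, adjusted p 4.37e-14), 19 oxidative phosphorylation genes (2.35e-11) and 6 glucocorticoid-responsive genes (0.00113). The authors' lower genes held 8 synaptic plasticity genes (0.00355), among them Reln and Cacna1c. These libraries chose the authors' genes, so the overlaps are not independent evidence. Within groups, the mean variance of the authors' deposited library values was 0.00880, against 0.103 for log2 values from the counts of the same genes.

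**Figure D3:**
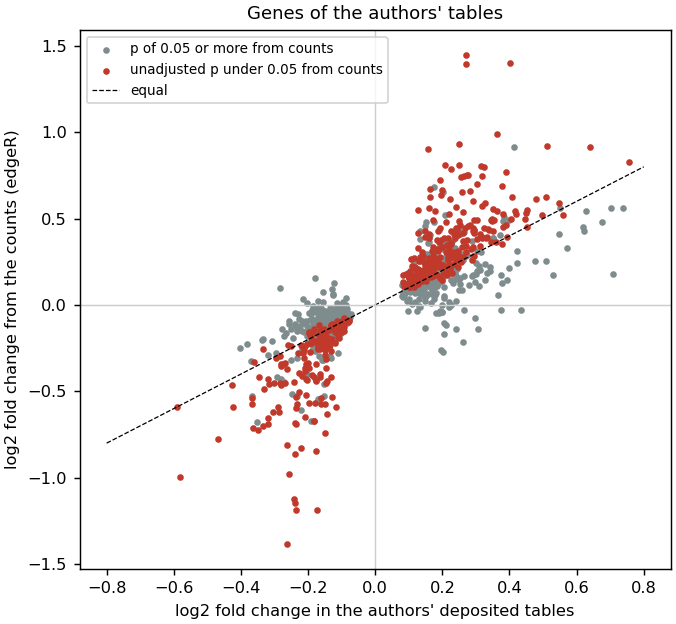
Each point is 1 of 1025 genes of the authors' deposited tables, with the deposited log2 fold change on the x axis and that from the counts on the y axis, in red where the unadjusted p from the counts was under 0.05 (444 genes). The dashed line marks equal values, and 96.1% of the genes have the same sign.

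**Figure D4:**
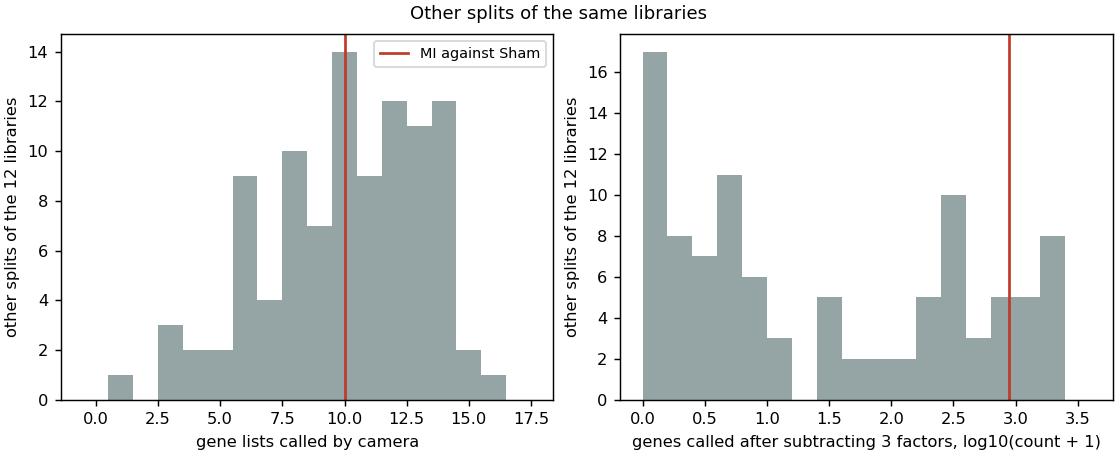
Grey bars count the other splits of the 12 libraries by the number of gene lists called by camera (left) and by the number of genes called after subtracting 3 surrogate variables, as log10 of the count plus 1 (right), and red lines mark MI against Sham. MI against Sham called 10 lists, with at most 16 in another split, and 878 genes after subtraction, with at most 2357 in another split.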

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

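The tests of the myelin list, of the meningeal score and of the number of lists below were chosen after the results were seen; the interaction test and its rearrangements were written down before they were run, but after the libraries had been split by sex-linked counts.

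MI minus Sham differed between the libraries with Y-linked counts and those with Xist for 2 genes (edgeR quasi-likelihood interaction, adjusted p 0.0476 for both). Both genes are named after their values were seen. At an unadjusted p under 0.05 the interaction held 1386 genes. Trh, which encodes thyrotropin-releasing hormone, had 19.2 ± 3.38 CPM in Sham 1, Sham 2 and Sham 3, 0.62 ± 0.15 in the MI libraries with Y-linked counts, 0.72 ± 0.53 in the MI libraries with Xist and 0.46 ± 0.30 in the Sham libraries with Xist (SD, n = 3 each), a difference of log2 fold changes of -5.51 (SE 0.68). Gpr37, a receptor of myelinating oligodendrocytes, had a difference of 0.77 (SE 0.09). Of 100 rearrangements of the sex-linked sets within MI and within Sham, the real one included, 4 gave as many genes. The highest other gave 3. That share lies under 0.05, but only 100 of 200 possible rearrangements were drawn, and the sets were formed after the data were examined. Chance is therefore not excluded for the count of 2.

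In the 6 libraries with Y-linked counts taken alone, edgeR called 211 genes, 101 higher and 110 lower in MI. Among them were 15 myelin genes on the higher side and 4 fibroblast and meningeal genes on the lower side. In the 6 with Xist it called 0, and no other tool was run there. Of 16975 genes tested in the latter, 216 had an unadjusted p under 0.05. That share lies below the 0.05 expected by chance, so the 0 does not show that an effect is absent. Of the 211 calls 204 were tested in the Xist libraries, where 66.7% had the same sign. Their median change in the same direction was 0.06 there, against 0.81 in the libraries that called them. The genes were picked for passing in the libraries with Y-linked counts, which raises their size there. This comparison alone therefore cannot show a difference between the sets. The 10 splits of 6 libraries, the real one included, are too few for a share under 0.05. The real split gave 211 and the highest other 0, so the 1 split as large was the real one. Adding the meningeal score as a covariate left 1 call and moved the median size of the change to 0.64, but the score parts all MI from all Sham libraries there, by a gap of 0.95, so meningeal tissue and the surgery cannot be told apart in these 6 libraries. A difference between the sets may exist for a few genes, given the 2 interaction calls, but a shared handling of Sham 1, Sham 2 and Sham 3 stays open, and the sex of the animals is not stated.

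The myelin list was higher in MI, with Mbp, an abundant member named after its values were seen, at 2442 ± 204 CPM in MI and 1667 ± 496 in Sham (SD, n = 6 each). The list did not pass camera with an estimated correlation (adjusted p 0.154) or the exact permutation test (adjusted p 0.189). In the exact test a single list could not pass after adjustment over 35 lists, so that outcome decides nothing. Its members moved together within groups, with an estimated inter-gene correlation of 0.781, which is consistent with a varying amount of myelin-rich tissue in the dissected piece. The difference of differences between the sets was 0.70 log2. Its exact permutation p was 0.025 over 400 arrangements, with an adjusted p of 0.438 over 35 lists. With so few arrangements a single list could not pass after adjustment over 35 lists, whatever its values, so the adjusted p cannot decide. Passing after adjustment was made the criterion only after the unadjusted p had been seen. A difference between the sets therefore stays open. An effect of MI on oligodendrocytes stays open and was not separated from dissection by any test here. Of 100 splits of the 12 libraries, the real one included, 62 gave as many called lists as the 10 of MI against Sham. The other splits gave a median of 10 lists and at most 16, so chance cannot be excluded for the number of lists.

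Single libraries stood far from the rest of their group in 23 of 402 groups tested, where chance gives about 20.1. The values are log2 gaps to the nearest library. Among list scores, Sham 6 lay -0.35 from the next for interneurons, MI 5 0.54 for blood cells and MI 3 -0.052 for ER stress. In Sham 1 the gap was 3.33 for Rspo1, 0.50 for Bgn and 0.31 for Ptprc. In Sham 6 it was 0.73 for Jun, 0.25 for Rbbp5, 0.20 for Pdgfrb, 0.15 for Slc2a1 and -0.19 for Psma4. In Sham 2 it was 0.089 for Rps15 and -0.56 for Xaf1, in Sham 3 -0.22 for Arrdc2, in Sham 4 0.38 for Adssl1 and -0.67 for Calb1, and in Sham 5 -0.89 for Fam183b. In MI 1 it was 0.37 for Pvalb, -0.16 for Kat6b and -0.28 for Egln3, in MI 3 -0.28 for Aqp4, in MI 4 -0.17 for Kcnd3 and in MI 5 0.73 for Hbb-bs.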

How the results depend on the processing

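The alternatives by sex-linked set, by within-group components, by marker scores and without Sham 1 and Sham 6 were chosen after seeing the data; the others were fixed beforehand. The count of 0 genes held under each of those but DESeq2, which gave 11 (7 higher, 4 lower; 1.04% of the authors' genes); the cause was not tested. It was also 0 with the sex-linked set or the dentate and meningeal scores as covariates, without Sham 1 and Sham 6, and in the Xist libraries alone. Of the authors' genes tested, 99.1% had the authors' sign in the Xist libraries alone and 79.3% in the Y-linked libraries alone. The Y-linked libraries alone gave 211 (101 higher, 110 lower; 7.46% of the authors' genes). With 2, 3 or 4 within-group components as covariates there were 163 (89 and 74; 7.08%), 673 (407 and 266; 24.9%) and 1016 (591 and 425; 32.2%). These components were taken from the same libraries after the group means were removed. They can lower the spread within groups without absorbing any MI difference, which favours calls, and no splits were run with them. The 10 called lists became 0 with an estimated correlation, 0 by fry and 0 by its mixed test, and 8 to 14 when 1 library was left out. Without Sham 4 1 marker list passed the exact permutation test, and 0 to 1 did over all libraries left out. The dentate list turned direction under voom weights (adjusted p 0.62), without Sham 6 (0.637, in a range from 0.000837 to 0.637 over libraries left out) and without Sham 1 and Sham 6 (0.533). In the Xist libraries alone camera's direction turned for the precursor list (0.897) and the meningeal list (0.0982). With the replicate number as a block 0 genes and 12 lists were called. Whether the replicate numbers pair the libraries was not settled. Deviations of same-numbered libraries correlated from -0.35 to 0.40, and 3 of 6 MI libraries correlated best with their own number. The self-test recovered 28% of genes changed 1.2-fold in real counts, and 80% of those changed 1.5-fold, while the median fold of the authors' higher genes is 1.14.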

Other observations

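Apart from the interaction test, the splits, the fits with library-level factors and the genes called by sex-linked set in this part were chosen after the results they bear on had been seen.

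Genes called in the libraries with Y-linked counts alone, named here after their values were seen, included Trhr, the receptor of thyrotropin-releasing hormone, with a log2 fold change of -1.85 there and -0.22 in the Xist libraries (edgeR adjusted p 0.00875 in the former), beside Trh at -4.95 and 0.59. Mbp, a main protein of compact myelin, had 1.06 and 0.14, and Mobp, another myelin protein, 1.09 and 0.24. The difference between the sets passed its own test for Trh and not for Trhr, Mbp or Mobp.

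The authors' deposited tables list 1059 genes while edgeR called 0 from the counts, and 3 factors shared across genes hold 82.7% of the variance of the deposited minus the count-based library values. A candidate explanation is that library-level factors were removed from the values before the groups were compared: subtracting 3 surrogate variables and testing without them gave 878 genes, with 744 of the authors' 1025 tested genes among them, and the number 3 was picked from the 37 fits below. Of 100 splits of the 12 libraries, the real one included, 15 gave as many genes after the same subtraction, with at most 2357 in another, so chance cannot be excluded for the 878. The same subtraction gave 436 false calls over 16829 genes in real counts with mixed groups; in negative binomial counts its number of false calls changed with numerical rounding and is not given. An effect of MI too small for the test on counts stays open, and the sources used here do not say what the authors did.

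Over the 37 fits, 14 with factors subtracted gave 0 to 4213 genes and 23 with factors as covariates gave 0 to 1016, with 0 in 16 of the 23. The 1016 came from 4 within-group components as covariates, whose limit is given above. Subtracting 1, 2, 3, 4 or 5 surrogate variables gave 1, 117, 878, 1892 and 4213 genes, and the same variables as covariates in limma gave 0 for each number.

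Without subtraction MI against Sham gave 0 genes, a count that 100 of 100 splits reach by construction, so the splits say nothing about chance there. The highest other split gave 436, and a split with that many calls points to a structure of the samples, whose source was not tested. The 1270 genes at an unadjusted p under 0.05 were reached by 17 of 100 splits, with at most 3562, so chance cannot be excluded for that number.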
